A study of Orbilia oligospora with 2 samples.

How the data were processed

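DAP-seq was done on genomic DNA from hyphae of A. oligospora with Halo-tagged AoMbp1. The design holds 1 AoMbp1 library and 1 input library, taken from the sample titles. No replicate exists for either, so there is no spread between replicates and no test between the libraries. A library made with the tag alone was not analysed here.

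The values start from the authors' processed tables. The peak list gives for each peak the position, the pileup at the summit, a signal in reads or fragments per the file headers. It also gives a fold enrichment, a ratio of pileup over input background per the file headers, and the deposited -log10 p-value and -log10 q-value of the peak caller. The aligner, the peak caller, their versions and the handling of duplicates are not given in the sources used here. The motif table holds the deposited match score, p-value and q-value of each site. The authors' coverage table gives the percent of the genome covered at each depth, and their peak statistics give the percent of reads and of the genome in peaks. Read numbers, unmapped, mapped and duplicate reads were taken from the authors' alignment table as counts with a percent.

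The tables were checked before use. Peak lengths equalled end minus start plus 1 in all 150 peaks. All 22 genes that the tables name had the same coordinates in the RefSeq gene table, which therefore served for gene positions and for linking scaffolds to locus tags. The input background at each peak was recovered as (pileup + 1) / fold enrichment - 1. The Poisson tail probability from this background and the pileup differed from the deposited -log10 p-value by at most 0.000371 in the 150 peaks. The lowest background, 24.8, was shared by 22 peaks and was taken as the genome-wide level. It may be a floor set by the peak caller, so the local input at these peaks may lie below it.

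Of 83494270 AoMbp1 reads that entered alignment 77019180 mapped, and of 64573710 input reads 63020247 mapped. Reads were of 150 bp from both ends. At this depth the 95% Wilson intervals of the shares of mapped, unmapped and duplicate reads were at most 0.0158 percentage points wide. Intervals for shares of peaks or sites are exact binomial at 95%. All intervals cover counting error only. Those for peaks treat peaks as independent, although 119 of the 150 lay on 1 scaffold, so intervals over all peaks are too narrow.

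Peaks were described for the scaffold with most peaks, the scaffold with the highest input background and the others. Scaffolds with at least 10 annotated genes were used for positions relative to the outermost genes, and a peak counted as outside when its summit lay before the start of the first gene or after the end of the last gene. Scaffold lengths were not at hand. The length of the genome was bounded from the total peak length of 109394 bp and its deposited 0.28% share, which gave at most 39.8 Mb. This bound assumes that the share was taken over the whole assembly, which the sources used here do not state. The gene spans of those scaffolds and the known extent of the others were subtracted, and what was left, at most 596 kb, bounds the sequence outside the outermost genes.

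The genes named are those assigned by the authors to the 15 peaks with the highest fold enrichment, with ties broken by q. Added to them were all assigned genes on the lists of cell cycle and division, DNA replication and repair, transcription factors and chromatin, signalling, stress response, and cell wall and adhesion. Up to 3 from each other list, and AoMbp1 and AoSwi6 where a peak was assigned, complete the rule. Lists were patterns on product descriptions. These choices, the gene lists and the elements searched were fixed before the data were examined.

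Median fold enrichment of peaks with and without an AT-rich site was compared by a two-sided permutation test of 100000 resamples, exact where a class had fewer than 10 peaks, with Benjamini-Hochberg adjustment over 3 sets of peaks. This replaced the planned test on ACGCGT and was chosen after seeing the data. It was repeated with values permuted only within the 3 classes of scaffolds. On 400 simulated sets made by shuffling the fold enrichments over all 150 peaks, the test called 3% at p under 0.05, and with a 1.1-fold increase put in it called 85%. These sets used fewer resamples and ignored scaffold classes. The rates therefore do not cover a motif tied to scaffold class, nor the tests within smaller sets of peaks. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

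Alternatives were a q under 0.01, a fold enrichment of at least 5, promoters of 1 kb and 500 bp, any overlap of a peak with a promoter, leaving out the 2 scaffolds of high input background, motif sites with q under 0.05, and other rules for assigned genes and for peaks outside the outermost genes. The genome sequence was not analysed here. The planned tests of ACGCGT frequency and position and the random placement of peaks were therefore left out. Gene list enrichment was left out because product descriptions were at hand only for the assigned genes.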

Results

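AoMbp1 of the nematode-trapping fungus Arthrobotrys (Orbilia) oligospora was expressed with a Halo tag and mixed with the fungus's own genomic DNA, and the DNA it retained was sequenced (DAP-seq). Mbp1 proteins carry a KilA-N type DNA-binding domain. In budding yeast Mbp1 works with Swi6 in the MBF complex, which binds the ACGCGT element upstream of genes transcribed as cells enter S phase. The comparison was 1 AoMbp1 library against 1 input library of the same genomic DNA, so the differences between libraries are given as values without a test.

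The authors called 150 AoMbp1 peaks, but these were spread very unevenly over the genome. A single scaffold, NW_011645605.1, carried 119 of them (79.3%), and the scaffold NW_011645625.1 carried 6. The remaining 25 peaks lay on 18 other scaffolds. The 119 peaks of NW_011645605.1 were broad and weakly enriched, with a median length of 593 bp and a median fold enrichment over input of 1.53 (range 1.25 to 3.29). The 25 peaks elsewhere were narrow, with a median length of 238 bp, and their median fold enrichment was 3.60 (range 1.56 to 13.6). All 9 peaks with an enrichment of at least 5-fold belonged to these 25. In all, 119 of the 150 peaks stayed under 2-fold, and 110 of those lay on NW_011645605.1.

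The 2 scaffolds also stood apart in the input. The input background that the authors' fold enrichment implies was 24.8 (pileup) at 22 of the 25 peaks on the other scaffolds, which was the lowest value at any peak. A value this uniform may be a floor of the peak caller, with the local input at or below it. On NW_011645605.1 the median background was 212, or 8.52 times that level, and on NW_011645625.1 it was 722, or 29.1 times that level. The peaks of NW_011645605.1 ran from position 60 to position 170353 and covered 59.3% of that stretch. The annotation places 1 gene on it, AOL_s00048g1, with the symbol YMF40 and a description matched to orf785 of the fungus Allomyces macrogynus. Whether this scaffold is multicopy DNA, such as mitochondrial DNA, was not tested. NW_011645625.1 also has 1 annotated gene, AOL_s00068g1, described as a hypothetical protein, and its 6 peaks were enriched 1.20- to 1.39-fold.

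**Figure D1:**
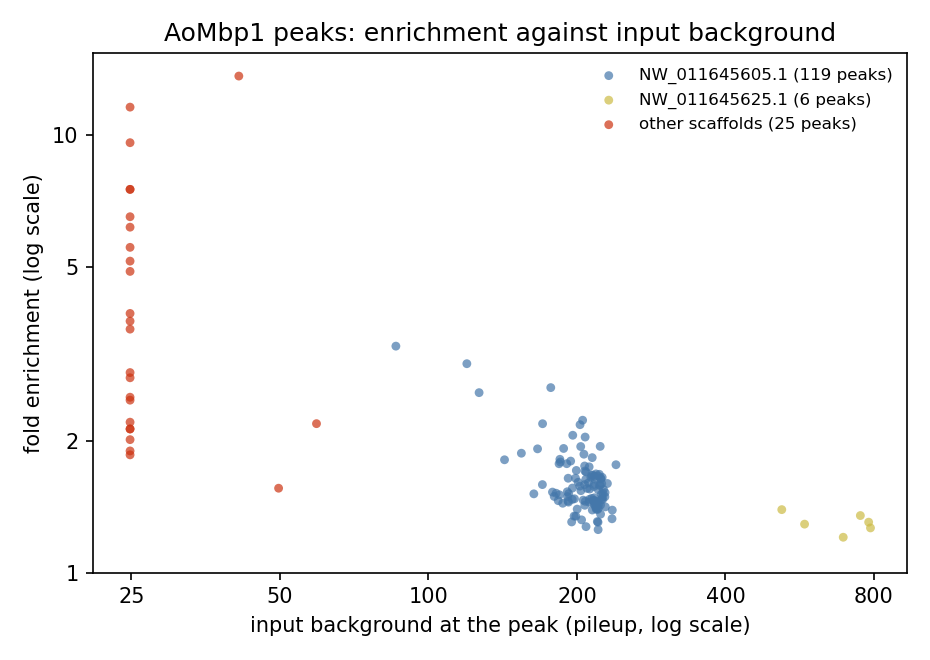
Each point is 1 of the 150 AoMbp1 peaks; the x axis is the input background recovered from the deposited pileup and fold enrichment (pileup, log scale), the y axis the fold enrichment (ratio, log scale). The 119 peaks of NW_011645605.1 lie between 1.25- and 3.29-fold at raised background, and the peaks above 5-fold lie on other scaffolds.

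The strongest peaks were intergenic sites before the first or after the last annotated gene of their scaffold. The highest, peak 139, was enriched 13.6-fold (pileup 575) at positions 1607297 to 1607594 of NW_011645637.1, 12670 bp beyond the last annotated gene, and no gene was assigned to it. Peak 135 followed at 11.6-fold, with its summit 1442 bp upstream of AOL_s00078g1, which encodes a protein of the adenine nucleotide alpha hydrolase type. Peak 132, at 9.60-fold, lay 2911 bp past AOL_s00075g243, the last gene of NW_011645632.1, and was left without an assigned gene. Peaks 1 and 145 had the same pileup of 193 and the same enrichment of 7.51-fold. Peak 1 was assigned to AOL_s00004g1, a TPR domain protein, and peak 145 to the histone H4 gene H4.1 (AOL_s00117g1). Histone H4 is a core component of nucleosomes. The summit of peak 145 lay 1464 bp past the 3' end of this gene.

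Among the genes with a peak upstream of the start, the strongest after AOL_s00078g1 was Dctn5 (AOL_s00006g1; 6.50-fold, 1994 bp upstream), named for a subunit of the dynein activator dynactin. The tof1 gene (AOL_s00043g1) had a 6.15-fold peak 1154 bp upstream. Its description is topoisomerase 1-associated factor 1; Tof1 proteins protect stalled replication forks. AOL_s00109g209, a DUF887 protein, had a 5.53-fold peak 1187 bp upstream. Further down the ranking stood AOL_s00170g1, a glyoxalase or dioxygenase family protein (4.88-fold, downstream), the hypothetical protein AOL_s00169g1 (3.91-fold, downstream) and AOL_s00076g19, a But2 domain protein (3.60-fold, 535 bp upstream). Peak 148 (5.15-fold), 461 bp past AOL_s00169g272, and peak 141 (3.75-fold), 9793 bp past AOL_s00097g648, had no assigned gene. The last of the 15 highest peaks, peaks 4 and 36 on NW_011645605.1 (3.29- and 3.0-fold), had none either. Their recovered input backgrounds were 85.9 and 120, under the median of 212 for the peaks of that scaffold. Their pileups of 285 and 361 lay on either side of its median of 322.

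**Figure D2:**
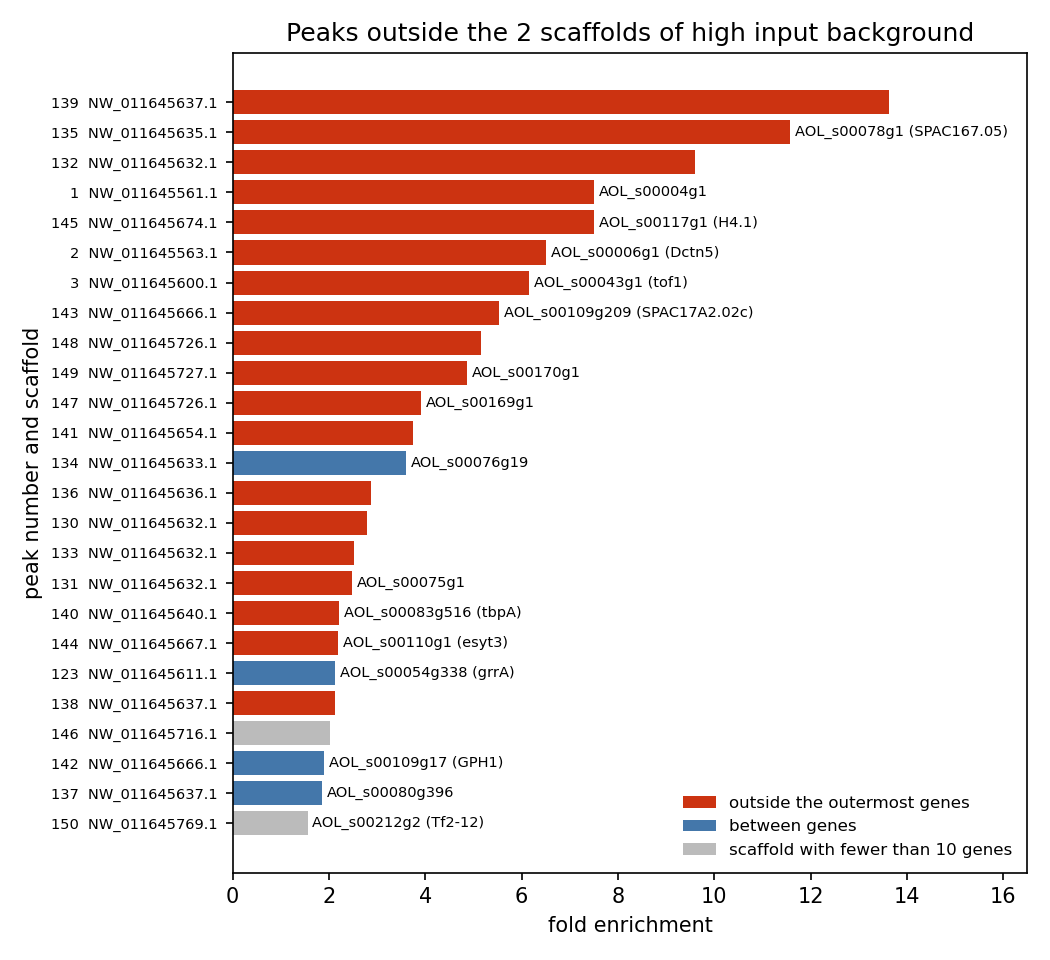
Fold enrichment (ratio, x axis) of the 25 peaks outside NW_011645605.1 and NW_011645625.1, 1 bar per peak, with the gene the authors assigned beside the bar. Red bars mark peaks outside the outermost annotated genes of scaffolds with at least 10 genes, and all 9 bars that reach 5-fold are red.

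The position of these peaks relative to the gene map was examined after the ranking had been seen. Of the 25 peaks, 23 lay on scaffolds with at least 10 annotated genes. Of these 23, 11 lay before the first gene and 8 after the last gene, which makes 19 peaks (82.6%, 95% interval 61.2 to 95.05) in 16 of the 56 stretches outside an outermost gene. On the same scaffolds, the sequence outside the outermost genes comes to at most 1.51% of the total, by an upper bound from the deposited peak statistics. That bound assumes that the deposited genome share was taken over the whole assembly. The median distance from summit to outermost gene was 1994 bp (range 461 to 12670). Of the 11 peaks before a first gene, 7 had their summit within 1 kb of the first base of the scaffold. The 4 peaks between genes reached 1.86- to 3.60-fold, against a median of 4.88-fold (range 2.13 to 13.6) for the 19. Of the 15 genes assigned on these scaffolds, 11 were the first or last gene of their scaffold, which follows from the position of the peaks.

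In the authors' annotation of all peaks, 129 (86.0%, 95% interval 79.4 to 91.1) were distal intergenic. Promoters, up to 2 kb upstream of a gene start, held 10 (6.67%, 3.24 to 11.9), regions downstream of genes another 10, and exons 1. No peak fell in an intron, an untranslated region or a first exon. NW_011645605.1 contributed 116 of the distal peaks, so the intervals over all peaks, which treat peaks as independent, are too narrow. Among the 25 peaks on the other scaffolds, 9 were in promoters (36.0%, 17.97 to 57.5), 6 downstream, 1 in an exon and 9 distal, so the promoter share depended on whether the 2 scaffolds of high input background were counted. With a promoter of 1 kb, 4 peaks remained, and with 500 bp 1 peak.

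The 21 peaks with an annotated position were assigned to 18 genes, of which 11 carried a symbol. Of the 11 gene lists fixed beforehand, 2 had members by product description. The DNA replication and repair list held 2 genes, tof1 and Tf2-12 (AOL_s00212g2). The latter matched through the words DNA polymerase, but its description is a reverse transcriptase of the kind retrotransposons carry. Its peak lay in exon 2 at 1.56-fold, the lowest enrichment among the 25. The list of transcription factors and chromatin held H4.1. The lists for cell cycle and division, signalling, stress response, cell wall and adhesion, secreted hydrolases, membrane traffic, transporters, metabolism and translation had no member by description among the 18. When GO and KEGG terms were searched too, a choice made after seeing the data, the cell cycle and division list went from 0 to 2 members, tof1 and grrA (AOL_s00054g338). Membrane traffic then had 2 members, tbpA (AOL_s00083g516) and H4.1, and secreted hydrolases 1, H4.1. DNA replication and repair rose to 3 with AOL_s00048g1, and transcription factors and chromatin to 2 with tbpA. These additions rest on matched terms alone: the description of H4.1 is a histone and that of tbpA a proteasome subunit. No assigned description named Mbp1 or Swi6.

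The 3 assigned genes that follow, and the single genes of the 2 scaffolds of high input background, were chosen for mention after their values were seen. The gene grrA had a 2.13-fold peak 844 bp upstream. Another gene, AOL_s00054g337, lay nearer to the summit of this peak, at 820 bp. The product of grrA is a subunit of the SCF ubiquitin ligase, a complex that marks G1 cyclins for degradation in yeast. The gene annotated tbpA, for a regulatory subunit of the 26S proteasome, had a 2.21-fold peak 765 bp upstream. GPH1 (AOL_s00109g17), for glycogen phosphorylase, had a 1.90-fold peak downstream. Enrichment of gene lists was not tested, since product descriptions were at hand only for the assigned genes.

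The authors' motif search gave 2 motifs and 199 sites. The AT-rich motif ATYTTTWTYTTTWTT had 143 sites in 49 peaks (32.7%, 95% interval 25.2 to 40.8), and 91.7% of the matched bases were A or T. The GC-rich motif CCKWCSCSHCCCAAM had 56 sites in 28 peaks (18.7%, 12.8 to 25.8). The 2 motifs were distributed differently. The AT-rich motif was found in 16 of the 25 peaks on the other scaffolds (64.0%, 42.5 to 82.0), in 33 of the 119 on NW_011645605.1 (27.7%, 19.9 to 36.7) and in none of the 6 on NW_011645625.1. The GC-rich motif was found in all 6 peaks of NW_011645625.1, with 30 of its 56 sites, and in 3 of the 25. Peak 128 of NW_011645625.1 alone held 17 of these sites. Peak 139, the most enriched, had no site of either motif. All sites lay within 228 bp of a summit, although 37 peaks were longer than 1 kb, so the absence of a site holds only near summits.

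None of the 199 sites contained the ACGCGT element, its relaxed form WCGCGW, or the related elements CACGAAA and CRCGAAA. The core CGCG occurred at 4 positions in 4 peaks. These counts cover the 2174 bases inside motif sites, or 1.99% of the peak sequence. These bases were picked for matching 2 other motifs, and 143 of the 199 sites match the AT-rich one. The lack of ACGCGT in them was therefore largely set in advance and says nothing on binding to it. The rest of the peak sequence was not analysed here, so the frequency of ACGCGT in the peaks remains open.

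AT-rich sites occurred in series. Peaks outside the outermost genes carried the motif in 14 of 19 cases, and 9 of these peaks held at least 3 sites. Among the 4 peaks between genes, 2 carried it and none held 3. The highest-scoring site, ATCTTTATCTTTATT (score 18.6), lay in the peak upstream of tof1. The longest run of overlapping sites, 87 bp, lay in peak 145 near H4.1. Leaving out shifts of 1 bp, neighbouring sites on the same strand of a peak started 6 bp apart in 34 of 78 pairs, 10 pairs were 3 bp apart, 67 of the 78 distances (85.9%) were multiples of 3 bp and 45 (57.7%) were multiples of 6 bp. The motif has a 6 bp period itself, which favours such shifts among overlapping matches.

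**Figure D3:**
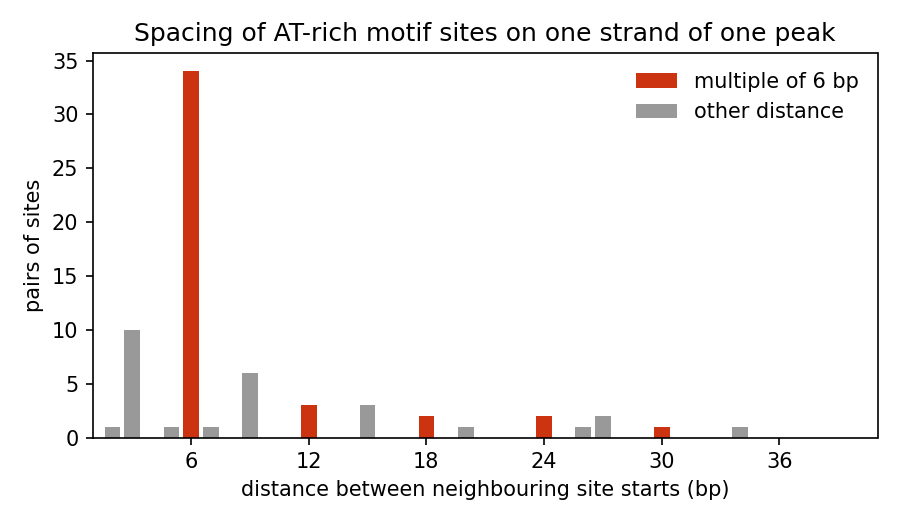
Number of pairs of neighbouring AT-rich motif sites (y axis) by the distance between their starts in bp (x axis, shown up to 40 bp), on the same strand of the same peak and without distances of 1 bp. The tallest bar is at 6 bp with 34 pairs.

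Over all scaffolds, peaks with an AT-rich site had a higher median enrichment than peaks without, but the call did not hold within classes of scaffolds. The median fold enrichment was 1.68 over 49 peaks with a site and 1.52 over 101 peaks without, a difference of 0.157 (two-sided permutation test, p = 0.00419; adjusted p = 0.0126 over 3 sets of peaks). When values were permuted only within scaffold classes, the call was lost (permutation p = 0.253), and such permutations gave a median difference of 0.1175. It was also lost on the -log10 q scale (permutation p = 0.129). Within NW_011645605.1 the medians were 1.56 over 33 peaks and 1.52 over 86, and the difference of 0.0425 did not pass the test (permutation test, p = 0.429; adjusted p = 0.429). On the other scaffolds the medians were 5.01 over 16 peaks and 2.13 over 9, a difference of 2.88 that also missed the threshold (exact permutation test, p = 0.0588; adjusted p = 0.0881). Peaks are not replicates, and the motif was found by the authors in these same peaks.

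The libraries differed in how many distinct fragments they held. Of the mapped reads of the AoMbp1 library, 85.2% were duplicates, against 10.6% in the input, or 8.06 times the share. Without duplicates, 11375858 of the 77019180 mapped AoMbp1 reads were left, and 56353885 of the 63020247 mapped input reads. The unmapped share was 7.76% in the AoMbp1 library and 2.41% in the input. GC content of the filtered bases was 41.5% and 43.8%. At least 10 reads covered 99.5% of the genome in the AoMbp1 library and 99.6% in the input, but at least 30 reads covered 71.6% and 99.5%. The peaks held 4.07% of the AoMbp1 reads on 0.28% of the genome. NW_011645605.1 made up 92.3% of the peak length and 81.9% of the summed summit pileup, at a median background 8.52 times the genome-wide level. The 25 peaks on the other scaffolds made up 6.94% of that pileup. The share of input reads in the peaks was not computed here, so the 4.07% does not measure enrichment over input.

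**Figure D4:**
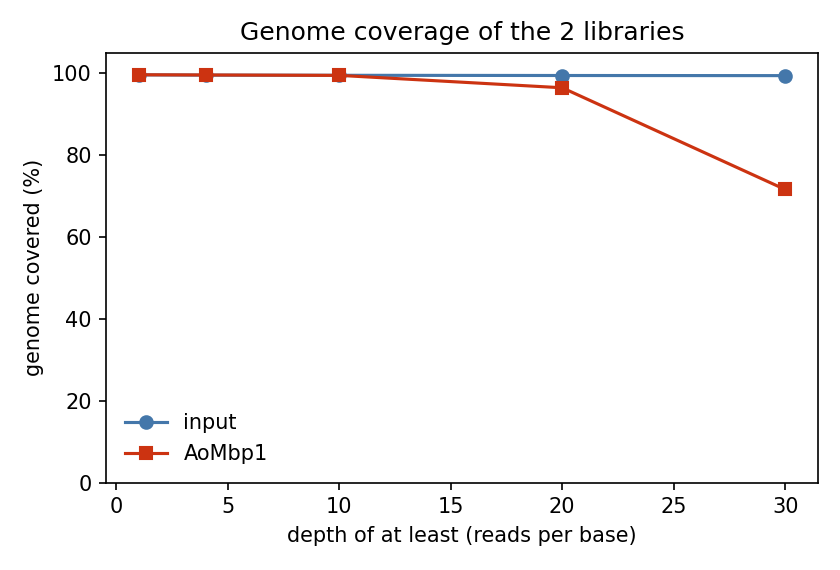
Percent of the genome (y axis) covered by at least the number of reads on the x axis, for the input library (circles) and the AoMbp1 library (squares). At a depth of 30 the input covers 99.5% and the AoMbp1 library 71.6%.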

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

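The shares of duplicate and unmapped reads drew attention because the AoMbp1 library differed from the input in these read statistics, which no comparison of peaks uses. The patterns described after them concern peaks and motif sites. The share of duplicates was 85.23% of mapped reads in the AoMbp1 library against 10.58% in the input. The share of unmapped reads was 7.76% against 2.41%, or 3.22 times as high. Where the unmapped reads came from was not analysed here. All tests below were chosen after seeing the data. The test of the AT-rich motif within NW_011645605.1 was set before its own result was seen, and the others after. The test of distances between sites was limited to sites that do not overlap after the distances of all sites had been seen.

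The first pattern is the concentration of weak peaks on NW_011645605.1. Of its 119 peaks, 104 had a lower fold enrichment than 1.86, the lowest called at the genome-wide background, which restates their weakness. The deposited -log10 p-values followed from pileup and background alone, to within 0.000371. By that rule a given fold enrichment reaches a smaller p at a higher background. The raised background therefore made these weak peaks easier to call. How many of them would have been called at a background of 24.8 was not computed. Whether the whole scaffold was in excess in the AoMbp1 library, in place of separate binding sites, was not tested. Whether the AT-rich motif sets the enrichment there stays open, as the medians differed by 0.0425 with a permutation p of 0.429. A high copy number, as in mitochondrial or other multicopy DNA, is a candidate explanation for an input background 8.52 times the genome-wide level, and the values do not separate preferential binding by AoMbp1 from a difference in library preparation.

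The second pattern is the position of 19 of 23 peaks outside the outermost genes of their scaffolds. Chance placement is argued against, since the share was 54.7 times the largest share of sequence that can lie there, under the same assumption on genome length. Extra copies of these stretches in the genomic DNA are argued against for most peaks, since the recovered background did not exceed the genome-wide level at 89.5% of them (17 of 19). That level may be a floor of the peak caller, so an excess that left the local input under it would not be seen. Peak 139, the strongest, was at 1.66 times that level and peak 144 at 2.39 times. Binding of AoMbp1 to sequence in these stretches may be the reason, but unequal amplification of AT-rich DNA in a library with 85.23% duplicates, or binding of such DNA by the tag or the beads, was not tested.

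The third pattern is the series of AT-rich sites within peaks. A tandem repeat of 6 bp remains possible but undecided: among sites that do not overlap, 36.4% of the distances (8 of 22; 95% interval 17.2 to 59.3) were multiples of 6 bp, but 14 of the 22 were multiples of 3 bp, so a 3 bp period would give a similar share. The sites may belong to low-complexity sequence, since 88.9% of the plus-strand sites (72 of 81) were printed wholly in lower case, as reference sequences mark repeats, against 0 of 41 for the GC-rich motif; partly or wholly in lower case were 76 of 81 and 13 of 41. Minus-strand sites were all in upper case and say nothing on this. No biological explanation was tested.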

How the results depend on the processing

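Of 28 alternative values, 10 kept their side of the threshold or stayed within counting error (counts: near the main count); those marked here as added were chosen after seeing the data. Peak number was 9 at a fold enrichment of at least 5 and 25 without the 2 scaffolds of high input background (added), by construction of smaller sets. The promoter share of 6.67% became 2.67% with 1 kb, 0.667% with 500 bp, 44.4% at 5-fold and 36.0% without the 2 scaffolds (added). The alternatives that follow were added. Restricting motif sites to q under 0.05 left 121 of 199, and the share of peaks with the AT-rich motif fell to 23.3%. That share was 64.0% without the 2 scaffolds and 88.9% at 5-fold. The median difference in enrichment between peaks with and without the AT-rich motif was not called by the permutation test within NW_011645605.1 (0.0425), on the other scaffolds (2.88, with fewer peaks) and on the -log10 q scale (3.11, permutation p = 0.129), where the cause was not tested. With permutation within scaffold classes the difference of 0.157 was not called either (permutation p = 0.253). Peaks outside the outermost genes made up 100% at 5-fold, and 79.2% to 86.4% under the 3 other alternatives. Assigned genes numbered 6 at 5-fold and 11 with promoter or exon peaks only. Genes on the fixed lists numbered 6 once GO and KEGG terms were searched too, against 3. The alternatives on ACGCGT frequency, position and enrichment and on the background of the gene lists were not run, because the sequence and the descriptions of all genes were not analysed here. A single library of each kind limits every value. Only 11375858 mapped AoMbp1 reads were not duplicates, and whether duplicates entered the peak calls is not given in the sources used here. If the genome-wide background of 24.8 is the mean coverage of the AoMbp1 library, it corresponds to 171 bp per read pair without duplicates and to 25.2 bp with them, less than the read length of 150 bp; on that assumption duplicates were not kept. At the genome-wide background no peak under 1.86-fold was called.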

Other observations

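The values in this part were examined after the peaks and sites had been seen. On 2 scaffolds, peaks lay both before the first and after the last gene. NW_011645632.1 had peaks 130 and 131 (2.79- and 2.48-fold) before its first gene and peaks 132 and 133 (9.60- and 2.52-fold) after its last. NW_011645726.1 had peak 147 (3.91-fold) before its first gene and peak 148 (5.15-fold) after its last. In 10 of the 14 peaks outside the outermost genes that carry the AT-rich motif, most sites had their T-rich strand running away from the annotated genes, and in 4 toward them (two-sided exact sign test, p = 0.180). By sites, 76 of 95 ran away from the genes, but sites of the same peak are not independent, and 11 of the 19 sites running toward them lay in peak 149 alone.

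The annotation of downstream peaks was uneven between strands. All 10 peaks called downstream belonged to genes on the minus strand. A pair of peaks that start within 3 kb past the end of a plus-strand gene, peaks 132 (2775 bp) and 148 (338 bp), were called distal intergenic. Counting both strands gave 12 downstream peaks, a value from a rule chosen after seeing the data. Both peaks are among the 9 of at least 5-fold, and neither received a gene in the authors' list.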
